A study of Homo sapiens with 18 samples.

How the data were processed

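Total RNA of U-87MG cells, an established human glioblastoma line, was measured on 1-colour Affymetrix arrays with biotin-labelled cDNA. The 18 arrays fell into 6 groups of 3. Cells carried either an empty vector or a vector for IL4I1, a secreted enzyme that oxidises aromatic amino acids. Each kind was combined with a non-targeting hairpin (shCtrl) or with 1 of 2 hairpins against the aryl hydrocarbon receptor AHR (shAHR1 and shAHR2). All cells had been cultured for 120 hours before RNA was taken. The labels name the 3 arrays of a group as biological replicates and describe them as separate experiments on stable lines. They do not say how many independent infections stand behind a group.

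The deposited values are log2 expression per probe set that the authors made with the oligo package and RMA, per the labels' list of processing tools; their versions are not given in the sources used here. RMA corrects the background, makes the distributions of the arrays alike and summarises the probes of a set, so a shift of all transcripts together cannot be seen in such values. The scale is not written beside the values; medians between 6.46 and 6.53 on every array and values from 1.11 to 13.4 were read as log2. No array was centred per gene. Scanner files were not used here.

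Of 18913 probe sets, 15598 were paired with 1 gene symbol, 870 with several, and 2445 were not listed in the annotation table and stayed unnamed. Probe sets with several symbols were not named. Old symbols were replaced through unique synonyms in the RefSeq gene table of assembly GRCh38.p14 in 1173 cases, and 58 gene symbols were not listed there. No coordinates were printed because the build behind the array annotation was not given. Where a gene had several probe sets, the one with the highest mean over all arrays was kept; this applied to 66 genes, and in 0 of them did the probe sets differ in the call of IL4I1 in shCtrl cells. The 15529 resulting genes were tested. CYP1A1 was not analysed here.

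Each gene was fitted in R 4.3.3 with limma 3.58.1 (lmFit and eBayes), in a model of 6 group means over all 18 arrays, so that all groups shared 1 estimate of the spread per gene. Genes with a Benjamini-Hochberg adjusted p under 0.05 were called, and errors of log2 changes are standard errors from this fit. The comparisons were IL4I1 against empty vector in each of the 3 hairpin backgrounds, each AHR hairpin against shCtrl with and without IL4I1, the interactions of IL4I1 with shAHR1, with shAHR2 and with the mean of both, and IL4I1 cells with each AHR hairpin against the shCtrl cells without IL4I1, a contrast the study's design text describes. The number of arrays, 3 per group, limits the precision: the median standard error of a log2 change was 0.220, and an exact permutation test of 3 against 3 arrays cannot give a p under 0.1.

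The design, the alternatives and 20 gene lists were fixed before the data were examined. The lists covered AHR core targets, wider AHR-responsive genes, AHR machinery, tryptophan and aromatic amino acid metabolism, ATF4 and amino acid response, NRF2 and oxidative stress, interferon response, cytokines and NF-kB, antigen presentation, cell cycle, extracellular matrix and motility, hypoxia and glycolysis, cholesterol synthesis, p53 targets, senescence and growth factors, neural and glial markers, immune cell markers, epithelial and embryonic kidney markers, ribosomal proteins, and reference genes. Each was tested in each comparison with limma's camera at a preset inter-gene correlation of 0.01, 240 tests in all, adjusted together. An adjusted p under 0.05 was reached by 69 of them. With an estimated correlation 5 of these held, and with fry, which tests only whether a list's own genes move 1 way on balance, 28 held. The 5 were the AHR core list under shAHR1 without IL4I1, under each hairpin with IL4I1, and with IL4I1 in shCtrl and shAHR2 cells.

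Genes named in the text followed a fixed rule. AHR, IL4I1 and the measured AHR core targets were named throughout. In each comparison up to 10 rising and 10 falling genes with the largest change were taken, among called genes whose 3 arrays per group did not overlap and whose brighter group reached the median of all probe sets (6.46). Small RNAs, olfactory receptors, receptor segments and unnamed or antisense transcripts were left out. For both hairpins together, genes were ranked by the smaller change. Up to 4 members of each list with the lowest adjusted p were added. A few genes outside the rule are marked as chosen after their values were seen. No background reading was used here. Of 189 named genes, 24 had a group mean in the lowest 1% of all group means (4.51 or less on the log2 scale), and the report gives no size for changes from or to such levels, a limit chosen after the values were seen.

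The fits were tested on simulated data made from the genes' own means and spreads, with 200 changed among 15529 genes in each of 5 runs. For IL4I1 in shCtrl cells the fit recovered 4.48% of changes of 0.5, 57.3% of changes of 1 and 94.2% of changes of 2 on the log2 scale. For the interaction with the mean of both hairpins it recovered 0% of changes of 0.5, 21.5% of changes of 1 and 85.3% of changes of 2. No call had the wrong direction. Over the 5 runs, unchanged genes were called 31 times for IL4I1 in shCtrl cells and 13 times for that interaction. The simulation gave a gene the same spread in all groups, so recovery may be lower where a group varies more.

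Replicate numbers were compared across groups by correlating the arrays' deviations from their group means. Every same-numbered pair exceeded 0.1 only between shCtrl and shAHR1 cells without IL4I1 (0.162, 0.181 and 0.249), so the numbers were taken to pair arrays in that comparison alone, from the data and not from the labels. The alternatives were a filter on dim genes, the mean of a gene's probe sets, all probe sets, only the groups compared, a replicate block, quantile normalization, median centring, limma with trend and robust, array weights, a minimum change, and each array left out in turn.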

Results

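The data were log2 expression levels of 15529 named genes on 18 arrays of U-87MG glioblastoma cells. The 6 groups of 3 arrays crossed IL4I1 expression (absent or present) with shCtrl, shAHR1 or shAHR2. Arrays had medians of 6.46 to 6.53 on the log2 scale and correlated with each other between 0.865 and 0.954, and 0 arrays held identical values. Replicate 2 of the shCtrl cells without IL4I1 stood apart in its relative log expression, with an interquartile range of 0.529 against 0.319 to 0.472 on the others.

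Both engineered genes followed the labels on every array. AHR, a ligand-activated transcription factor, averaged 10.14 ± 0.09 (SD, n = 3) in shCtrl cells and 10.02 ± 0.27 in shCtrl cells with IL4I1. All 12 arrays with an AHR hairpin lay between 7.45 and 8.16. Without IL4I1, AHR fell by 2.27 ± 0.16 (SE) under shAHR1 and by 2.23 ± 0.16 under shAHR2 on the log2 scale (limma adjusted p = 3.2e-06 and 4.4e-06). With IL4I1 it fell by 1.98 ± 0.16 and 2.41 ± 0.16 (adjusted p = 1.7e-05 and 1.3e-06). IL4I1, which encodes a secreted L-amino acid oxidase, lay between 5.27 and 6.43 on the 9 arrays without the transgene and between 12.67 and 13.01 on the 9 arrays with it. Its log2 change was 7.05 ± 0.22 in shCtrl, 6.76 ± 0.22 in shAHR1 and 6.80 ± 0.22 in shAHR2 cells (adjusted p = 1.2e-11, 2.3e-11 and 2.1e-11). AHR itself differed with IL4I1 by -0.11 ± 0.16, 0.18 ± 0.16 and -0.30 ± 0.16 in these backgrounds, none of which passed the test (adjusted p = 0.77, 0.72 and 0.50).

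**Figure D1:**
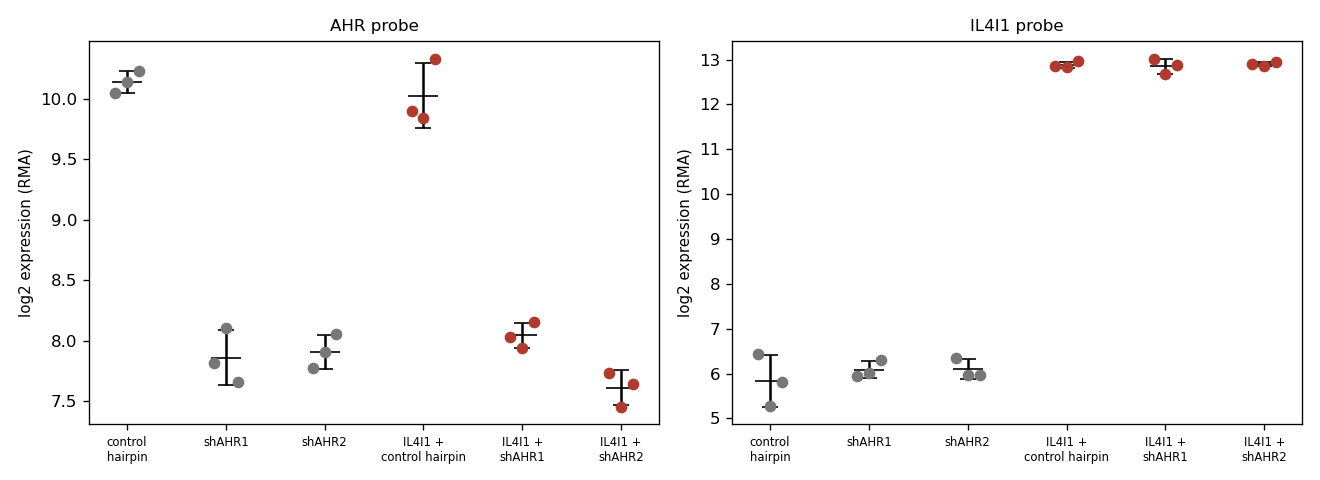
Log2 expression (RMA) of AHR (left) and IL4I1 (right) in the 6 groups; points are replicates 1 to 3 from left to right, grey without and red with IL4I1, and bars are the mean and SD of 3 arrays. AHR lies at 7.45 to 8.16 on all 12 arrays with an AHR hairpin, and IL4I1 at 12.67 or above on all 9 arrays with the transgene; the axes do not start at 0.

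The first comparison asked what IL4I1 changed in cells with normal AHR. With IL4I1, 10 of 29 cytokine and NF-kB genes and 3 of 9 AHR core targets rose, and 28 of 42 cell cycle genes fell. These lists passed camera, with adjusted p = 0.25, 0.027 and 0.25 with an estimated correlation. Among the genes taken by the naming rule, SLAMF9, a receptor of the SLAM family (3.49 ± 0.30, SE), and the cytokines IL24 (3.03 ± 0.43) and IL1A (2.97 ± 0.38) rose. The chemokine CCL20 (2.60 ± 0.37), the hair keratin KRT33B (2.66 ± 0.35) and PI3, the protease inhibitor elafin (2.40 ± 0.41), rose too, with limma adjusted p from 1.9e-05 for SLAMF9 to 0.0037 for PI3. MPV17L, a membrane protein related to MPV17, BPIFC and MST1R, the receptor tyrosine kinase RON, rose from means in the lowest 1% of all group means, where no size is given (adjusted p = 4.9e-06, 1.4e-04 and 0.012). Falls were seen in ESCO2, an acetyltransferase of cohesin (-3.28 ± 0.70), the histone H2BC14 (-3.15 ± 0.63), the condensin subunit NCAPG (-3.00 ± 0.51) and cyclin A2, CCNA2 (-2.94 ± 0.70). The spindle genes DLGAP5 (-2.91 ± 0.73) and KIF11 (-2.67 ± 0.57), ANLN of cytokinesis (-2.79 ± 0.62) and the mitotic kinase PBK (-2.78 ± 0.71) also fell. The histone H1-1 and the kinetochore gene NDC80 fell to means in the lowest 1%. The adjusted p of these falls ranged from 0.0036 for NCAPG to 0.041 for NDC80.

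In all, 313 genes rose and 398 fell in shCtrl cells with IL4I1 at a limma adjusted p under 0.05, 711 of 15529. Of these, 708 had no overlap between the 3 arrays of either group, as did 20.3% of all genes, where chance gives 10%. The number was 94 when only these 6 arrays entered the fit and 402 with a change of at least 1 on the log2 scale. It was 253 without shCtrl replicate 2, 324 without shCtrl replicate 3. It was 250 and 363 without replicates 1 and 2 of the IL4I1 cells.

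Among AHR core targets, 3 of 9 measured members rose with IL4I1 in shCtrl cells over all genes, and 7 rose adjusted over the list alone. They were TIPARP, a mono-ADP-ribosyltransferase that restrains AHR (1.55 ± 0.18, adjusted p = 1.8e-04), CYP1B1, a cytochrome P450 (1.18 ± 0.28, adjusted p = 0.023), and AHRR, the AHR repressor (0.71 ± 0.17, adjusted p = 0.029). The quinone reductase NQO1 (0.72 ± 0.20), the amino acid transporter SLC7A5 (0.83 ± 0.28), the drug exporter ABCG2 (0.60 ± 0.21) and NFE2L2, which encodes NRF2 (0.39 ± 0.15), were higher without passing over all genes. CYP1A2 (0.23 ± 0.35) and ALDH3A1 (-0.03 ± 0.25) were near their level without IL4I1. The list rose as a whole (median 0.71, camera adjusted p = 1.1e-05; adjusted p = 0.027 with an estimated correlation). Of 28 wider AHR-responsive genes 7 rose, and 12 adjusted over the list alone, among them the stanniocalcin STC2 (1.37 ± 0.22) and the collagenase MMP1 (2.08 ± 0.35). That list also rose (camera adjusted p = 2.1e-07; adjusted p = 0.25 with an estimated correlation).

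Stress and inflammatory lists also held genes that rose with IL4I1 in shCtrl cells. Of 34 genes of the ATF4 and amino acid response 6 rose, and 18 adjusted over the list alone. They included the tryptophanyl-tRNA synthetase WARS1 (1.12 ± 0.23), the transcription factor DDIT3 (1.73 ± 0.37), SESN2 (1.15 ± 0.26) and the pseudokinase TRIB3 (1.85 ± 0.43). The list median was 0.58 (camera adjusted p = 5.6e-12; adjusted p = 0.43 with an estimated correlation). Of 24 NRF2 targets 3 rose, the haem oxygenase HMOX1 (1.70 ± 0.31), the thioredoxin reductase TXNRD1 (0.90 ± 0.20) and the cystine transporter SLC7A11 (1.71 ± 0.47). Adjusted over the list alone 8 rose and 1 fell (camera adjusted p = 0.0019; adjusted p = 0.51 with an estimated correlation). Of 29 cytokine and NF-kB genes 10 rose, and 15 adjusted over the list alone, with CXCL2, a neutrophil chemokine (1.24 ± 0.22), beside IL1A, IL24 and CCL20 (camera adjusted p = 8.5e-10; adjusted p = 0.25 with an estimated correlation). Of 12 leukocyte markers 3 rose, the integrins ITGAX (0.97 ± 0.22) and ITGAM (1.20 ± 0.30) and the Fc receptor chain FCER1G (1.10 ± 0.27), 4 adjusted over the list alone (camera adjusted p = 0.044; adjusted p = 0.47 with an estimated correlation).

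The cell cycle list fell furthest: 28 of 42 members fell in shCtrl cells with IL4I1, and 39 adjusted over the list alone. The replicative helicase subunits MCM3 (-1.79 ± 0.32), MCM5 (-2.24 ± 0.41) and MCM4 (-1.32 ± 0.28) and the spindle gene NUSAP1 (-2.17 ± 0.46) had its lowest adjusted p, from 0.0051 for MCM3 to 0.015 for NUSAP1. Its median change was -1.98 (camera adjusted p = 1.1e-26; adjusted p = 0.25 with an estimated correlation). This list also spread widely within groups, with per-array medians from 0.12 to 1.74 on the 9 arrays without IL4I1 and from -1.51 to -0.03 on the 9 arrays with it. Of 20 neural and glial markers 4 fell, and 5 adjusted over the list alone: the growth factor receptor PDGFRA (-1.40 ± 0.26), the glutamate transporter SLC1A3 (-0.90 ± 0.19), SNAP25 (-0.92 ± 0.24) and GFAP, the intermediate filament of astrocytes (-0.74 ± 0.20). That list fell (camera adjusted p = 0.0091; adjusted p = 0.25 with an estimated correlation).

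The other lists did not pass camera in shCtrl cells with IL4I1. Matrix and motility genes went both ways, with MMP1 up and CCN2, a growth factor of the matrix (-1.42 ± 0.26), ITGA3 (-0.71 ± 0.14) and the proteoglycan VCAN (-0.90 ± 0.22) down. Of 46 members 1 rose and 3 fell, and 5 rose and 6 fell adjusted over the list alone (adjusted p = 0.95). Of 24 p53 targets 3 rose and 1 fell, and 7 rose and 1 fell adjusted over the list alone, with GDF15 (1.59 ± 0.41) and XPC (0.54 ± 0.14) up and DDB2 (-0.58 ± 0.14) down (adjusted p = 0.077). Of 24 genes of tryptophan and aromatic amino acid metabolism 1 rose, WARS1, and 2 adjusted over the list alone (adjusted p = 0.88). ADM (1.00 ± 0.24) and the hexokinase HK2 (0.63 ± 0.17) were the 2 genes that rose of 33 in hypoxia and glycolysis (2 adjusted over the list alone; adjusted p = 0.74). Of 25 genes of senescence and growth factors FGF2 rose (0.96 ± 0.18) and ANGPT1, an angiopoietin, fell to a mean in the lowest 1% of group means, with 1 rising and 2 falling adjusted over the list alone (adjusted p = 0.68). IFI35 (1.08 ± 0.25) was the 1 gene that rose of 31 interferon-induced genes (1 adjusted over the list alone; adjusted p = 0.89). ERAP2 (-0.72 ± 0.19) was the 1 that fell of 23 in antigen presentation (1 adjusted over the list alone; adjusted p = 0.10). LSS (-0.64 ± 0.14) was the 1 that fell of 20 in cholesterol synthesis, where 1 rose and 1 fell adjusted over the list alone (adjusted p = 0.69). No member changed, over all genes or adjusted over the list alone, among 10 AHR partners, 10 epithelial markers, 25 ribosomal proteins and 9 reference genes (camera adjusted p = 0.34, 0.14, 0.80 and 0.39). Medians and tests differed in sign for the interferon, matrix, hypoxia and ribosomal lists, whose medians were 0.08, -0.01, -0.01 and -0.02.

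The hairpin comparisons asked what loss of AHR changed in cells without IL4I1. Both hairpins lowered AHR, the monocarboxylate transporter family member SLC16A6 (-2.05 ± 0.35 under shAHR1 and -2.10 ± 0.35 under shAHR2), and the calcium-binding protein calretinin, CALB2 (-1.78 ± 0.33 and -2.16 ± 0.33). They lowered the amino acid transporter SLC7A8 (-1.50 ± 0.19 and -1.03 ± 0.19) and TMEM255B (-1.10 ± 0.23 and -1.26 ± 0.23). Both raised GLTP, a glycolipid transfer protein (1.25 ± 0.20 and 1.23 ± 0.20), STK40 (1.23 ± 0.21 and 1.20 ± 0.21) and WARS1 (1.32 ± 0.23 and 1.19 ± 0.23). Both raised PRKAA1, a catalytic subunit of AMP-activated kinase (1.19 ± 0.19 and 1.28 ± 0.19), and FBXL7 (1.16 ± 0.15 and 1.20 ± 0.15). SCRN1 (1.5 ± 0.18 and 1.14 ± 0.18), the actin-bundling protein LCP1 (1.05 ± 0.21 and 1.06 ± 0.21) and NNT, the mitochondrial transhydrogenase (1.05 ± 0.16 and 1.17 ± 0.16), rose as well. So did the transcription factor TCF4 (1.18 ± 0.23 and 1.04 ± 0.23) and LYRM1 (0.97 ± 0.15 and 0.94 ± 0.15). The limma adjusted p of these genes lay between 3.2e-06 for AHR and 0.048 for TMEM255B under shAHR1.

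Other genes were named for 1 of the hairpins by the naming rule, which does not mean that the other left them unchanged. The means of DCC and EFEMP1, named for shAHR2, were also higher under shAHR1. With shAHR1 the chemokine CCL2 (1.73 ± 0.24) and IL20RB, a cytokine receptor chain (1.5 ± 0.30), rose. The BMP antagonist GREM1 (-1.69 ± 0.26), CYP1B1 (-1.40 ± 0.28), AHRR (-1.27 ± 0.17), the WNT agonist RSPO3 (-1.21 ± 0.24) and the kinesin KIF21A (-1.12 ± 0.19) fell. With shAHR2 the netrin receptor DCC (2.11 ± 0.23), the nuclear receptor RORB (1.98 ± 0.29), TOX (1.84 ± 0.25), IGFBP5 (1.83 ± 0.27), EFEMP1 (1.65 ± 0.31), KCNIP4 (1.48 ± 0.32), E2F7 (1.27 ± 0.22) and PELI1 (1.24 ± 0.19) rose. ELAPOR1 (-1.45 ± 0.29), YRDC (-1.45 ± 0.23), the growth factor epiregulin, EREG (-1.41 ± 0.18), GK5 (-1.37 ± 0.26), CSGALNACT1 (-1.26 ± 0.25) and HLA-DQA2 (-1.15 ± 0.19) fell. The germ-cell RNA-binding protein DAZL rose under both, and SLC35F1 under shAHR2, from means in the lowest 1% of all group means, where no size is given. IGFBP5 also rose under shAHR1, by 1.35. Whether the hairpins differed from each other was not tested.

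The AHR core list fell under both hairpins without IL4I1. Under shAHR1, 3 of 9 members fell, AHRR, ABCG2 (-1.14 ± 0.21) and CYP1B1, and 4 adjusted over the list alone (camera adjusted p = 3.9e-05; adjusted p = 0.033 with an estimated correlation). Under shAHR2, 0 of 9 fell over all genes and 3 adjusted over the list alone (camera adjusted p = 0.0011; adjusted p = 0.085 with an estimated correlation). CYP1B1 (-0.83 ± 0.28), ABCG2 (-0.82 ± 0.21) and AHRR (-0.56 ± 0.17) were lower there. ABCG2 was dim, with a mean of 4.60 in shAHR1 cells. Its call under shAHR1 was lost in 4 of 6 fits with an array left out, but its calls with IL4I1 in 0 of 6 under each hairpin. TIPARP was -0.49 ± 0.18 and -0.24 ± 0.18 and did not pass. The ATF4 list, with WARS1 as its 1 member that rose under either hairpin (1 adjusted over the list alone under each), was higher under shAHR1 and shAHR2 (camera adjusted p = 4.7e-04 and 0.0075; adjusted p = 0.70 and 0.82 with an estimated correlation). In tryptophan metabolism QPRT, an enzyme of NAD synthesis (0.89 ± 0.17 and 0.92 ± 0.17), and WARS1 rose and SLC7A8 fell under both. Adjusted over the list alone 2 rose and 2 fell under shAHR1 and 4 rose and 1 fell under shAHR2 (camera adjusted p = 0.95 and 0.69). The p53 list was higher (camera adjusted p = 0.019 and 0.016; adjusted p = 0.55 and 0.53 with an estimated correlation), with 0 of 24 members called over all genes and 0 and 5 adjusted over the list alone. The hypoxia list was lower (camera adjusted p = 0.022 and 0.017; adjusted p = 0.73 and 0.72 with an estimated correlation), with 0 of 33 called over all genes and 1 and 2 adjusted over the list alone. Under shAHR1 the wider AHR list and the cholesterol list were also lower (camera adjusted p = 0.0052 and 0.0081; adjusted p = 0.57 and 0.59 with an estimated correlation). They had 0 members called over all genes. Adjusted over the list alone, 1 rose and 5 fell of 28, and 2 fell of 20.

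In counts, 46 genes rose and 17 fell under shAHR1, 63 in all, and 73 rose and 41 fell under shAHR2, 114 in all. Of these, 30 rose and 5 fell under both, against 0.216 and 0.0449 for independent lists. Simulated groups without any change, set against shared simulated controls, shared 0 calls. Groups without change yield almost no calls, so this 0 does not show how many calls common controls make shared. Log2 changes of the 2 hairpins correlated at 0.606 over all genes against a simulated 0.50, with a covariance of 0.0703 against 0.0366. With 3 shCtrl arrays the controls could not be split, so part of the excess may come from them. Fitted on the groups compared alone, each hairpin called 1 gene, shared by both, and trend and robust called 106 and 174 (53 shared). Without dim genes shAHR1 called 117 (53 shared), and a change of at least 1 left 64 for shAHR2 (23 shared). Without 1 array the shAHR1 count fell to 22 (shAHR1 replicate 3), 25 (shAHR1 replicate 1) or 33 (shCtrl replicate 2). The shAHR2 count fell to 44 (shCtrl replicate 2), 49, 51 or 54 (shAHR2 replicates 3, 2 and 1). The 35 shared calls fell to 18 without shCtrl replicate 2, to 18 and 17 without shAHR1 replicates 1 and 3, and to 23, 20 and 23 without shAHR2 replicates 1, 2 and 3.

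The same hairpins were compared in cells with IL4I1. The keratins KRT33B (-2.28 ± 0.35 under shAHR1 and -1.98 ± 0.35 under shAHR2) and KRT75 (-2.34 ± 0.39 and -2.89 ± 0.39) fell under both. PI3 (-1.73 ± 0.41 and -2.33 ± 0.41) and TIPARP (-2.10 ± 0.18 and -1.37 ± 0.18) fell as well. So did SLC16A6 (-3.10 ± 0.35 and -2.40 ± 0.35), the hyaluronan synthase HAS2 (-1.55 ± 0.31 and -1.43 ± 0.31), ZNF474 (-1.54 ± 0.27 and -2.0 ± 0.27) and CCNJ (-1.39 ± 0.29 and -1.94 ± 0.29). BPIFC fell from a mean of 6.62 to the lowest levels on the arrays (adjusted p = 1.3e-04 and 4.2e-05). Both hairpins raised MFAP4, a microfibril protein (1.75 ± 0.31 and 1.48 ± 0.31), KCTD4 (1.54 ± 0.29 and 1.36 ± 0.29) and STK40 (1.51 ± 0.21 and 1.36 ± 0.21). Both also raised INSYN2B (1.29 ± 0.19 and 1.63 ± 0.19), OLFML2A (1.61 ± 0.21 and 1.27 ± 0.21) and the transcription factor NFIA (1.61 ± 0.21 and 1.24 ± 0.21). PRKAA1 (1.24 ± 0.19 and 1.47 ± 0.19), UBE2H (1.25 ± 0.21 and 1.14 ± 0.21), the lysophosphatidic acid receptor LPAR1 (1.13 ± 0.18 and 1.33 ± 0.18) and SCRN1 (1.30 ± 0.18 and 1.10 ± 0.18) rose too. Limma adjusted p ranged from 1.7e-05 for TIPARP under shAHR1 to 0.046 for PI3 under shAHR1.

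Under shAHR1 BANK1 (1.71 ± 0.22), MCTP1 (1.60 ± 0.17), IFITM2 (1.52 ± 0.26) and ST8SIA1 (1.47 ± 0.28) rose in IL4I1 cells, and the imprinted gene MEST rose from a mean in the lowest 1% of group means, where no size is given. IL24 (-2.29 ± 0.43), IL1B (-2.06 ± 0.35), the interleukin 1 antagonist IL1RN (-2.12 ± 0.31) and GREM1 (-2.09 ± 0.26) fell. Under shAHR2 PDGFRA (1.65 ± 0.26), STON2 (1.56 ± 0.28), SLC35F1 (1.59 ± 0.34) and NNT (1.31 ± 0.16) rose, and GK5 (-1.75 ± 0.26) and the sphingosine phosphate receptor S1PR3 (-1.68 ± 0.24) fell. The AHR core list fell under shAHR1 (4 of 9 members, 4 adjusted over the list alone: TIPARP, AHRR at -1.15 ± 0.17, ABCG2 at -1.25 ± 0.21 and CYP1B1 at -1.37 ± 0.28; camera adjusted p = 3.1e-06, and adjusted p = 0.027 with an estimated correlation). Under shAHR2 2 of 9 fell, TIPARP and ABCG2 (-1.42 ± 0.21), and 4 adjusted over the list alone (camera adjusted p = 1.2e-04; adjusted p = 0.042 with an estimated correlation). Wider AHR-responsive genes fell as a list (8 and 4 of 28, 11 and 5 adjusted over the list alone; camera adjusted p = 1.8e-07 and 6.1e-04; adjusted p = 0.25 and 0.51 with an estimated correlation). The transglutaminase TGM2 (-1.84 ± 0.18 and -1.09 ± 0.18) and FGF2 (-1.13 ± 0.18 and -1.06 ± 0.18) fell in both.

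Of 29 cytokine and NF-kB genes, 7 fell under shAHR1 and 2 under shAHR2 in IL4I1 cells. The list median was -0.91 and -0.59 (camera adjusted p = 1.1e-11 and 1.2e-09; adjusted p = 0.25 under each with an estimated correlation). The 7 included the adhesion molecule VCAM1 (-0.98 ± 0.20) and IL33, which fell to a mean in the lowest 1% of group means, and adjusted over the list alone 18 fell and 1 rose. The 2 were CCL2 (-1.84 ± 0.24) and CCL20 (-1.60 ± 0.37), and 6 fell adjusted over the list alone. Among genes of senescence and growth factors ANGPT1 and IGFBP5 rose, from means in the lowest 1%, while FGF2 fell under both. Of that list 2 rose and 2 fell under shAHR1 and 2 rose and 1 fell under shAHR2, and adjusted over the list alone 2 rose and 3 fell, and 2 rose and 1 fell (camera adjusted p = 0.99 and 0.75). Smooth muscle actin, ACTA2 (0.94 ± 0.12 and 1.01 ± 0.12), rose and the collagen COL5A2 (-0.99 ± 0.17 and -0.80 ± 0.17) fell in the matrix list. Of this list 3 rose and 1 fell under shAHR1 and 1 rose and 3 fell under shAHR2 (5 and 4, and 4 and 4, adjusted over the list alone; camera adjusted p = 0.95 and 0.89). The p53 list was higher under both hairpins (1 and 2 of 24 rose, 3 and 5 adjusted over the list alone; camera adjusted p = 0.045 and 0.0031; adjusted p = 0.59 and 0.46 with an estimated correlation). Under shAHR2 the cell cycle list was higher (0 of 42 called over all genes or adjusted over the list alone; camera adjusted p = 1.8e-04; adjusted p = 0.78 with an estimated correlation). The cholesterol list was higher there (1 of 20 rose, 3 rose and 1 fell adjusted over the list alone; camera adjusted p = 0.031; adjusted p = 0.63 with an estimated correlation). The hypoxia list was lower there (0 of 33 called, 3 adjusted over the list alone; camera adjusted p = 3.1e-04; adjusted p = 0.57 with an estimated correlation).

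With IL4I1, 151 genes rose and 89 fell under shAHR1 (240 in all) and 119 rose and 76 fell under shAHR2 (195 in all); 59 rose and 34 fell under both. Independent lists would share 1.16 and 0.436. Simulated groups without change again shared 0, which does not show the part of common controls. The correlation of changes was 0.645 against a simulated 0.501 and the covariance 0.0839 against 0.0367; the 3 control arrays are again shared and could not be split. Of the genes shared by both hairpins in each background, 17 were called in the same direction in all 4 comparisons. AHR, SLC16A6 and TMEM255B fell, and ACTA2, CLIC2, DAZL, EMP1, FBXL7, IGFBP5, LINC00520, NNT, PRKAA1, QPRT, S100A11, SCRN1, SNAP23 and STK40 rose. CLIC2, EMP1, LINC00520, S100A11 and SNAP23 among them were named after their values were seen. Fitted on the groups compared alone, the counts were 17 for shAHR1 and 39 for shAHR2 (7 shared). A change of at least 1 left 128 and 109 (55 shared), and array weights gave 399 for shAHR2. Without 1 array they fell, for shAHR1, to 82 and 119 (replicates 1 and 2 of the IL4I1 shCtrl cells) and to 122, 99 and 144 (shAHR1 replicates 1, 2 and 3). For shAHR2 they fell to 78 and 90 and to 97, 81 and 75 in the same order. The 93 shared calls fell to 39 and 44 without replicates 1 and 2 of the IL4I1 shCtrl cells, to 59 and 59 without shAHR1 replicates 1 and 2, and to 57, 50 and 45 without shAHR2 replicates 1, 2 and 3.

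The remaining comparisons asked how far the IL4I1 response depended on AHR. Many genes responded to IL4I1 in AHR knockdown cells too. SLAMF9 (3.62 ± 0.30 in shAHR1 and 3.83 ± 0.30 in shAHR2 cells), MPV17L (2.10 ± 0.24 and 2.52 ± 0.24) and IL24 (2.05 ± 0.43 and 2.54 ± 0.43) rose in both. IL1A (1.80 ± 0.38 and 2.15 ± 0.38) and ATP6V0D2, a subunit of the vacuolar proton pump (2.00 ± 0.43 and 2.29 ± 0.43), did so too. In shAHR1 cells the neuropeptide gene NMB (2.21 ± 0.26), GCNT3 (2.03 ± 0.43), the glucose transporter SLC2A10 (2.01 ± 0.38) and NRXN3 (1.82 ± 0.39) also rose. The mitotic genes PLK1 (-2.77 ± 0.60) and CDC20 (-2.70 ± 0.59) fell there, and NDC80, PBK, CDK1 and KIF20A fell to means in the lowest 1% of group means, where no size is given. PRR11 (-2.43 ± 0.52), the ribonucleotide reductase RRM2 (-2.43 ± 0.54) and PRC1 (-2.40 ± 0.55) fell as well. In shAHR2 cells KRT86 (2.35 ± 0.26), TRIM77 (2.35 ± 0.44), SLC16A6 (2.05 ± 0.35) and the cytokine IL36B (1.82 ± 0.19) rose. H2BC14 fell in both (-3.02 ± 0.63 and -3.20 ± 0.63). In shAHR2 cells CCL2 (-2.49 ± 0.24), the growth factor FGF7 (-2.17 ± 0.36), NEGR1 (-1.85 ± 0.31), E2F7 (-1.72 ± 0.22), CCN2 (-1.36 ± 0.26), NR2F1 (-1.33 ± 0.19), GABRA3 (-1.24 ± 0.26) and PAK3 (-1.24 ± 0.25) fell, and DCC fell to a mean in the lowest 1%. Adjusted p in limma lay between 7.2e-06 for SLAMF9 in shAHR2 cells and 0.046 for NDC80 in shAHR1 cells.

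By lists, AHR core targets rose with IL4I1 in both kinds of knockdown cells. In shAHR1 cells 4 of 9 rose, AHRR (0.84 ± 0.17), NQO1 (0.98 ± 0.20), CYP1B1 (1.20 ± 0.28) and NFE2L2 (0.63 ± 0.15), 4 adjusted over the list alone (camera adjusted p = 3.1e-04; adjusted p = 0.054 with an estimated correlation). In shAHR2 cells 2 rose, AHRR (0.81 ± 0.17) and NQO1 (0.95 ± 0.20), and 4 adjusted over the list alone (camera adjusted p = 1.0e-05; adjusted p = 0.027 with an estimated correlation). TIPARP was -0.06 ± 0.18 and 0.42 ± 0.18 and did not pass in either. NRF2 targets rose (2 and 1 of 24, 12 and 7 adjusted over the list alone; camera adjusted p = 6.3e-12 and 2.3e-07; adjusted p = 0.092 and 0.25 with an estimated correlation), with TXNRD1 (1.05 ± 0.20 and 1.10 ± 0.20) in both. The ATF4 list had 0 called members over all genes, and 1 and 9 of 34 adjusted over the list alone (camera adjusted p = 1.3e-07 and 8.4e-11; adjusted p = 0.57 and 0.47 with an estimated correlation). The cell cycle list fell, with 16 of 42 members in shAHR1 and 0 of 42 in shAHR2 cells over all genes and 41 and 39 adjusted over the list alone (medians -1.91 and -1.70; camera adjusted p = 1.4e-35 and 4.8e-28; adjusted p = 0.25 in each with an estimated correlation). Limma counted 2046 and 1855 genes of any kind at an unadjusted p under 0.05. Of the cytokine genes IL24 and IL1A rose and CCL2 (-2.03 ± 0.24 in shAHR1 cells) fell in both. Adjusted over the list alone 3 rose and 2 fell in shAHR1 and 8 rose and 1 fell in shAHR2 cells, and the list rose in shAHR2 cells (camera adjusted p = 0.75 and 3.1e-04; the latter had adjusted p = 0.55 with an estimated correlation). The wider AHR list rose (1 rose and 1 fell of 28 in shAHR1 and 2 rose in shAHR2 cells, 8 rose and 1 fell and 7 rose and 1 fell adjusted over the list alone; camera adjusted p = 8.0e-04 and 6.7e-05; adjusted p = 0.52 and 0.43 with an estimated correlation). The p53 list rose with 0 of 24 members called, over all genes or adjusted over the list alone (camera adjusted p = 0.025 and 0.0016; adjusted p = 0.57 and 0.43 with an estimated correlation). Neural markers fell in shAHR1 cells (1 of 20, 1 rose and 3 fell adjusted over the list alone; camera adjusted p = 0.041; adjusted p = 0.32 with an estimated correlation). Epithelial markers rose in shAHR2 cells with 0 of 10 called either way (camera adjusted p = 0.042; adjusted p = 0.48 with an estimated correlation).

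**Figure D2:**
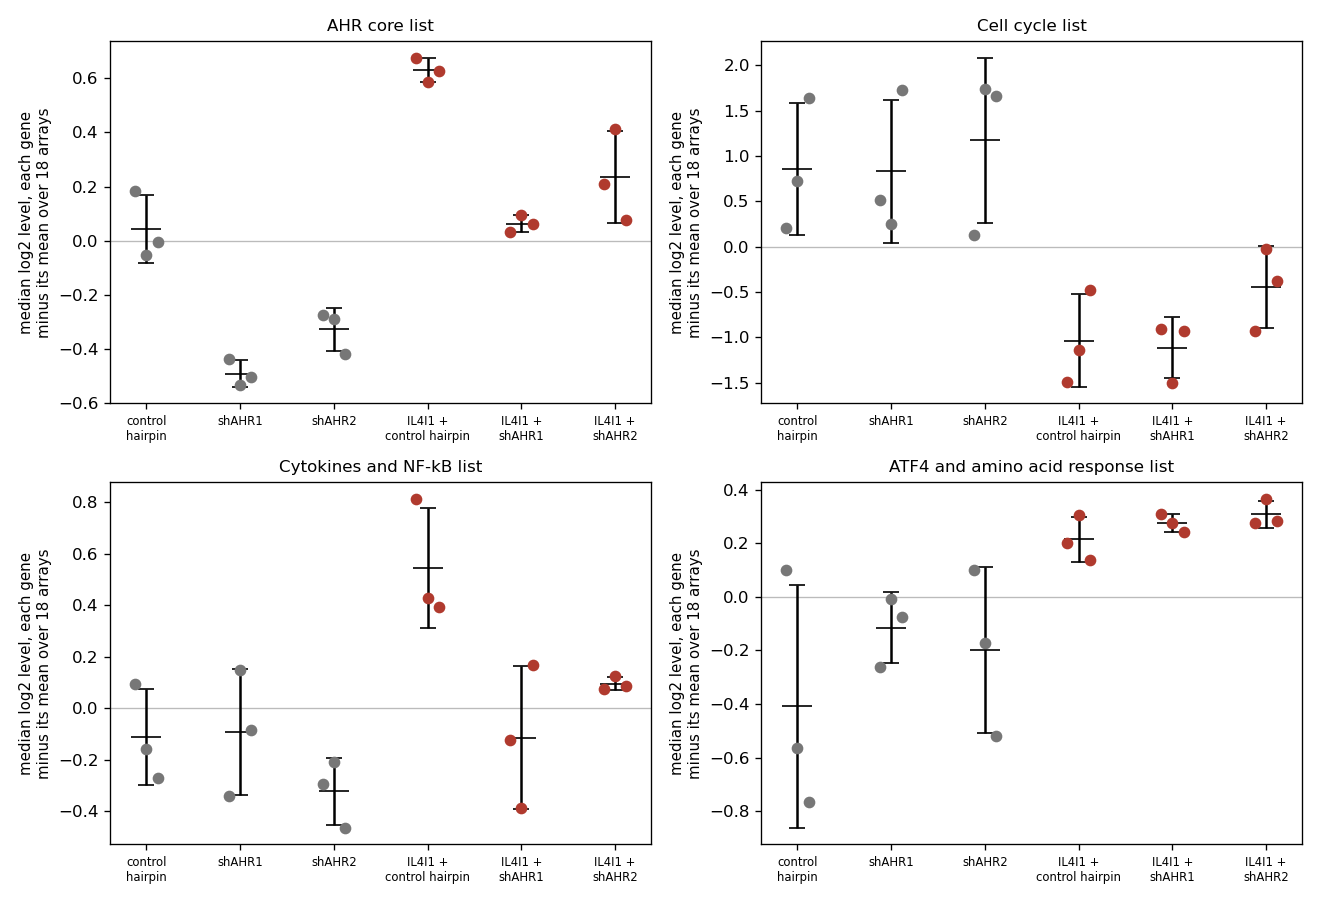
Median log2 level per array of 4 gene lists, each gene taken relative to its mean over 18 arrays, in the 6 groups; points are replicates 1 to 3 from left to right, grey without and red with IL4I1, and bars are the mean and SD of 3 arrays. The AHR core list lies higher with IL4I1 in each hairpin background, and the cell cycle list at 0.12 to 1.74 without and -1.51 to -0.03 with IL4I1.

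In counts, IL4I1 raised 87 and lowered 117 genes in shAHR1 cells (204 in all) and raised 52 and lowered 43 in shAHR2 cells (95 in all), and 56 were shared in 1 direction. In shAHR2 cells 54.7% of calls were higher, but 48.5% of 130 calls with quantile normalization. Of the 711 genes called in shCtrl cells, 652 kept their sign in shAHR1 cells and 676 in shAHR2 cells. The slope of their changes through 0 on the change in shCtrl cells was 0.672 and 0.654. Left-out arrays gave slopes from 0.541 to 0.751 and from 0.545 to 0.788. Genes chosen in the knockdown cells instead gave 1.01 and 0.951, but choosing genes on the vertical axis favours higher slopes. With the knockdown change on the horizontal axis, the same genes gave 0.870 (shCtrl on shAHR1) and 0.912 (shCtrl on shAHR2). All genes, on the change in shCtrl cells, gave 0.483 and 0.497. Over all genes the knockdown responses on each other gave only 0.519 (shAHR2 on shAHR1) and 0.566 (shAHR1 on shAHR2). Noise in the change on the horizontal axis lowers such slopes, so they do not measure a smaller response. The slopes of 1.01 and 0.951 do not show an equal response either. The counts were 43 and 23 when fitted on the groups compared alone, 353 and 198 with trend and robust, and 372 and 235 with the replicate number as a block. In shAHR2 cells array weights gave 462 and leaving out dim genes 147. Without 1 array the shAHR1 count was 54 and 34 (replicates 1 and 3 without IL4I1), and 121, 42 and 90 (replicates 1, 2 and 3 with IL4I1). The shAHR2 count was 335, 35 and 22 (replicates 1, 2 and 3 without IL4I1), and 29, 26 and 31 (with IL4I1).

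**Figure D3:**
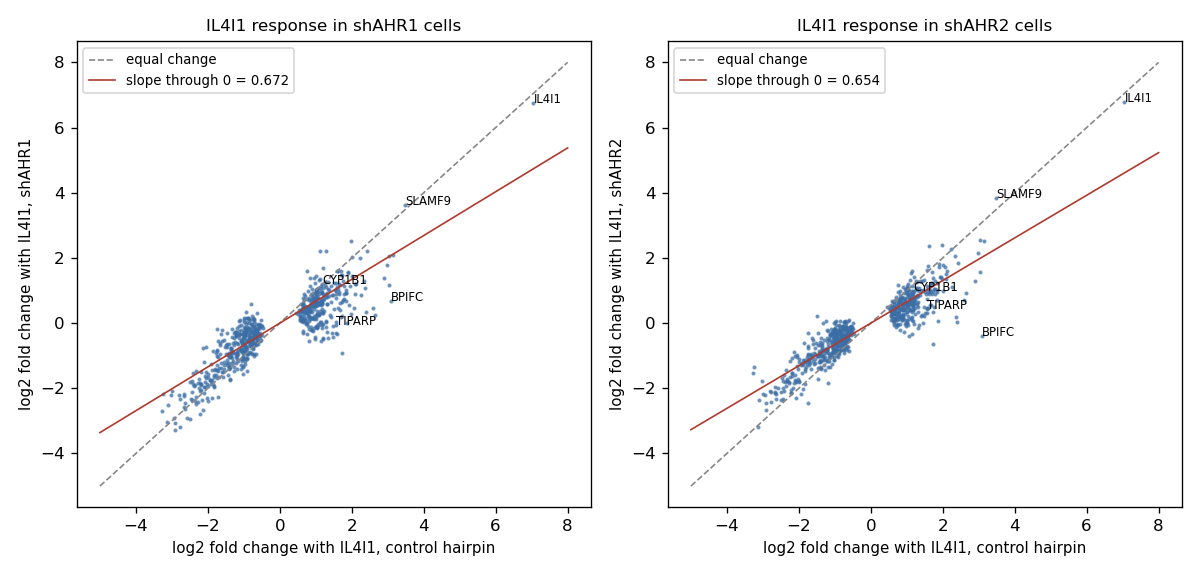
Log2 fold change with IL4I1 in shAHR1 (left) and shAHR2 cells (right) against that in shCtrl cells for the 711 genes called in shCtrl cells; the dashed line marks equal change and the red line the slope through 0. The slopes are 0.672 and 0.654, and choosing the genes on the horizontal axis favours slopes below 1.

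Tested directly, few genes passed for a different IL4I1 response between backgrounds. The interaction with shAHR1 called 0 genes in limma, with 901 at an unadjusted p under 0.05, 4 with trend and robust and 1 without dim genes. That with shAHR2 called 2, BPIFC and CCL2 (-2.49 ± 0.34, each adjusted p = 0.016). It called 1 with quantile normalization or with trend and robust, and 0 without dim genes or on the groups compared alone. That with the mean of both hairpins called 3, BPIFC (adjusted p = 0.021), CCL2 (-2.26 ± 0.29, adjusted p = 0.013) and TIPARP (-1.37 ± 0.22, adjusted p = 0.048). BPIFC averaged 6.62 ± 0.38 (SD, n = 3) in IL4I1 shCtrl cells and between 2.66 and 3.52 in the other groups, each in the lowest 0.0837% of all group means, so no size is given for its difference. CCL2, a monocyte chemokine, averaged 6.42 ± 0.46 in shCtrl cells and 6.42 ± 0.36 with IL4I1, but 8.15 ± 0.19 against 6.12 ± 0.29 in shAHR1 and 7.06 ± 0.21 against 4.57 ± 0.20 in shAHR2 cells. TIPARP averaged 7.66 ± 0.07 and rose to 9.21 ± 0.20 in shCtrl cells, against 7.17 ± 0.17 and 7.11 ± 0.32 in shAHR1 and 7.42 ± 0.23 and 7.84 ± 0.12 in shAHR2 cells. For CYP1B1 and AHRR the interaction was -0.09 ± 0.34 and 0.12 ± 0.21 (adjusted p = 0.99 for each). Leaving out 1 array ended the call in the mean of both hairpins in 2 of 18 cases for CCL2 (replicates 2 and 3 of the IL4I1 shCtrl cells), 8 of 18 for BPIFC and 15 of 18 for TIPARP. Quantile normalization ended the calls of BPIFC and TIPARP, trend and robust that of BPIFC, and array weights that of TIPARP. The interaction with the mean of both hairpins called 0 genes without replicate 2 or 3 of the IL4I1 shCtrl cells. It called 1 without their replicate 1, without replicate 1 or 2 of the IL4I1 shAHR2 cells, or without replicate 1 of the shAHR1 cells. The interaction with shAHR2 called 0 without replicate 1 or 2 of the shAHR2 cells, replicate 2 or 3 of the shCtrl cells, replicate 3 of the IL4I1 shCtrl cells or replicate 1 of the IL4I1 shAHR2 cells, and 1 without replicate 2 or 3 of the last. The interaction with shAHR1 called 3 genes without shCtrl replicate 1 and 1 without replicate 2 or 3.

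Among lists, the cytokine and NF-kB response to IL4I1 was lower in knockdown cells (median interaction -0.93 with shAHR1, -0.42 with shAHR2 and -0.58 with the mean of both; camera adjusted p = 1.5e-11, 3.8e-05 and 4.8e-10; adjusted p = 0.25, 0.50 and 0.25 with an estimated correlation). Of its 29 members 0, 1 and 1 passed over all genes, the 1 being CCL2, and 7, 2 and 4 adjusted over the list alone. The response of the wider AHR list was lower too (median -0.29 with the mean of both; 0 of 28 called, 2 adjusted over the list alone; camera adjusted p = 0.0041; adjusted p = 0.57 with an estimated correlation). It was lower with shAHR1 and with shAHR2 as well (0 of 28 called, 2 and 0 adjusted over the list alone; camera adjusted p = 0.0078 and 0.021; adjusted p = 0.59 and 0.62 with an estimated correlation). With shAHR1 and with the mean of both the ATF4 response was lower (camera adjusted p = 0.016 and 0.018; adjusted p = 0.84 in each with an estimated correlation). In the same interactions that of antigen presentation was lower (camera adjusted p = 0.023 and 0.031; adjusted p = 0.65 and 0.68 with an estimated correlation). That of NRF2 targets was higher there (camera adjusted p = 0.014 and 0.047; adjusted p = 0.59 and 0.63 with an estimated correlation). With shAHR2 the responses of the cell cycle list and of neural markers were higher (camera adjusted p = 0.042 and 0.034; adjusted p = 0.91 and 0.30 with an estimated correlation). None of these last 5 lists had a called member, over all genes or adjusted over the list alone. The AHR core list did not pass camera in any of these 3 interactions.

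Finally, IL4I1 cells with an AHR hairpin were set against shCtrl cells without IL4I1, as in the study's own design. WARS1 rose (1.93 ± 0.23 under each hairpin), as did SLAMF9 (3.73 ± 0.30 and 3.65 ± 0.30), SLC7A11 (1.94 ± 0.47 and 2.35 ± 0.47) and DDIT3 (1.98 ± 0.37 and 2.08 ± 0.37). IL20RB (2.63 ± 0.30), NRXN3 (2.54 ± 0.39), SLC2A10 (1.92 ± 0.38) and GDF15 (1.92 ± 0.41) rose with shAHR1. MMP1 (2.56 ± 0.35), CMKLR2 (2.19 ± 0.53) and the adhesion molecule NRCAM (2.14 ± 0.26) rose with shAHR2. MPV17L under both hairpins, and MST1R and the trypsin inhibitor SPINK1 with shAHR2, rose from means in the lowest 1% of group means, where no size is given. DLGAP5 (-3.25 ± 0.73), ASPM (-3.04 ± 0.68), CEP55 (-2.97 ± 0.63) and the topoisomerase TOP2A (-2.88 ± 0.71) fell with shAHR1. NCAPG (-2.12 ± 0.51), NUSAP1 (-1.90 ± 0.46), CDC45 (-1.66 ± 0.42) and ETNK1 (-1.52 ± 0.18) fell with shAHR2. PBK with shAHR1 and the helicase HELLS with shAHR2 fell to means in the lowest 1%. In limma 375 genes rose and 329 fell with shAHR1 (704 in all) and 335 rose and 185 fell with shAHR2 (520 in all), and 297 were shared in 1 direction, with 3 shCtrl arrays in common.

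Relative to that baseline the ATF4 list was high under both hairpins (9 and 10 of 34 rose, 17 and 21 adjusted over the list alone; camera adjusted p = 7.7e-13 and 4.7e-14; adjusted p = 0.42 and 0.37 with an estimated correlation). So was the p53 list (5 and 6 of 24, 11 rose and 2 fell, and 11 rose, adjusted over the list alone; camera adjusted p = 9.8e-05 and 2.5e-06; adjusted p = 0.26 and 0.25 with an estimated correlation). XPC (0.68 ± 0.14 and 0.80 ± 0.14) and SESN2 (1.14 ± 0.26 and 1.36 ± 0.26) rose in both. NRF2 targets were high (6 and 4 of 24 rose, 11 rose and 1 fell and 12 rose and 2 fell adjusted over the list alone; camera adjusted p = 3.1e-06 and 6.6e-04; adjusted p = 0.25 and 0.47 with an estimated correlation). The cell cycle list was low (24 and 3 of 42 fell, 40 and 20 adjusted over the list alone; camera adjusted p = 4.8e-28 and 3.3e-17; adjusted p = 0.25 and 0.43 with an estimated correlation). Neural markers were low with shAHR1 (1 rose and 2 fell of 20, 1 and 3 adjusted over the list alone; camera adjusted p = 0.034; adjusted p = 0.30 with an estimated correlation). With shAHR2 the wider AHR list was high (3 rose and 1 fell of 28, 6 and 1 adjusted over the list alone; camera adjusted p = 0.042; adjusted p = 0.68 with an estimated correlation). The hypoxia list was low there (0 of 33 called, 1 rose and 5 fell adjusted over the list alone; camera adjusted p = 0.021; adjusted p = 0.73 with an estimated correlation). Of AHR core targets NQO1 (0.85 ± 0.20 and 0.77 ± 0.20) rose under both hairpins and ABCG2 fell under shAHR2 (-0.82 ± 0.21). Leaving out an array ended that ABCG2 call in 5 of 6 cases. TIPARP (-0.55 ± 0.18 and 0.18 ± 0.18), CYP1B1 (-0.19 ± 0.28 and 0.16 ± 0.28) and AHRR (-0.44 ± 0.17 and 0.26 ± 0.17) did not pass. The counts were 166 and 66 when fitted on the groups compared alone, and 366 and 240 with a change of at least 1. Without replicates 2 and 3 of the shCtrl cells they were 265 and 366 with shAHR1 and 219 and 299 with shAHR2; without replicates 1, 2 and 3 of the IL4I1 cells they were 450, 240 and 431, and 227, 300 and 258.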

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

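The tests of the cell cycle list and of the size of the IL4I1 response were chosen only after the results were seen; the other splits of the arrays were planned before.

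Results below differed in their IL4I1 response between hairpin backgrounds by an interaction test. CCL2 had an interaction of -2.49 with shAHR2 and -2.26 with the mean of both hairpins on the log2 scale, and TIPARP of -1.37 with the mean of both. BPIFC passed both tests (adjusted p = 0.016 and 0.021), with no size given since 5 of its 6 group means lay in the lowest 0.0837% of all. With shAHR1 the list medians of the interaction were -0.36 for wider AHR-responsive genes, -0.24 for the ATF4 and amino acid response, 0.15 for NRF2 targets, -0.93 for cytokines and NF-kB and -0.16 for antigen presentation. With shAHR2 they were -0.23 for wider AHR-responsive genes, -0.42 for cytokines and NF-kB, 0.31 for the cell cycle and 0.23 for neural and glial markers. With the mean of both they were -0.29 for wider AHR-responsive genes, -0.20 for ATF4, 0.13 for NRF2, -0.58 for cytokines and NF-kB and -0.15 for antigen presentation. None of these list calls held with an estimated correlation. Outside the named genes, 112 of 3315 probe sets without a single gene name were called with IL4I1 in shCtrl cells, 68 higher and 44 lower.

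Other splits of the same arrays were refitted. For each comparison of 3 with 3 arrays the real split, 1 of 10, called the most genes, and 10 splits are too few for a share under 0.1. The real counts and the highest of the other splits were 711 and 0 for IL4I1 in shCtrl, 204 and 0 in shAHR1 and 95 and 0 in shAHR2 cells. They were 63 and 2 for shAHR1 and 114 and 10 for shAHR2 without IL4I1, 240 and 0 and 195 and 0 with IL4I1, and 704 and 1 and 520 and 1 against the shCtrl baseline. For the interactions, IL4I1 labels were exchanged within each hairpin in 100 splits. Such splits do not test chance there: exchanging more labels in 1 hairpin than in another turns the change with IL4I1 itself into an interaction, and exchanging some of them widens the spread. Of the 100, 100 gave at least the 0 genes found with shAHR1 (highest 275), a number every split must reach. With shAHR2 7 gave at least 2 genes (highest 1381), and with the mean of both hairpins 4 gave at least 3 (highest other 7). The split with 1381 genes exchanged all 6 shCtrl labels and no others, so it measured a sum of both responses. Whether chance gave the interaction calls stays open. The 35 and 93 genes shared by both hairpins without and with IL4I1 were each reached by 1 of 100 splits, the real one (highest other 0 and 79). Splits that mix knockdown with control arrays widen the spread, which by itself lowers the calls. They cannot exclude chance in the shared shCtrl arrays. The split with 79 kept the 3 shCtrl arrays as controls and exchanged arrays between the hairpins.

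The cell cycle list was lower with IL4I1 in every hairpin background. The noisiest array, shCtrl replicate 2, is argued against, as it takes no part in the change in shAHR2 cells, where the list changed by -1.62 (SE 0.533). Without IL4I1 the list lay at 0.12 to 0.51 on the replicates 1, at 0.25 to 1.74 on the replicates 2 and at 1.64 to 1.73 on the replicates 3. Each group holds replicates 1 to 3, so a growth state that adds equally to all arrays of a number cancels by design. The mean over same-numbered pairs equals the plain difference between arrays with and without IL4I1, so the pairs do not test such a state. All 9 same-numbered pairs were lower with IL4I1, by -1.06 to -2.66 (mean -1.82, SE over pairs 0.149). Any other pairing would be lower too, as every array with IL4I1 (highest -0.03) lay below every array without it (lowest 0.12). That SE treats the pairs as independent, though they come from 3 hairpin backgrounds. A growth state not shared by number was not tested. Differences between the stable lines apart from IL4I1 may still be a source, as an exact two-sided sign test over 3 backgrounds gave p = 0.25, the smallest it can give. A response to IL4I1 itself stays open as well.

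The IL4I1 response was larger in shCtrl than in shAHR cells when judged on the 711 genes called in shCtrl cells. Selecting genes by their change in shCtrl cells may account for this. Over all genes but IL4I1, covariances between responses that share no array gave a ratio of 1.25 (jackknife SE 0.328), which does not settle it, and 1.20 without shCtrl replicate 2. A need for AHR was not decided by the AHR core list, whose interaction with both hairpins was -0.0306 (SE 0.0966). Its per-array medians rose by 0.59, 0.55 and 0.56 in shCtrl, shAHR1 and shAHR2 cells, and the knockdown was incomplete.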

How the results depend on the processing

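The alternatives here were planned before the data were examined. No list call changed sign. Of 384 called pairs of a named gene and a comparison 0 changed sign, and 279 lost the call in at least 1 setting with all arrays. Of these, 277 lost it when only the groups compared entered the fit, which has fewer arrays to estimate the spread. Leaving out 1 array ended 228 calls. The shCtrl arrays without IL4I1 correlated with their own group at 0.919 to 0.920, the other arrays at 0.932 to 0.950. A spread shared by all groups may be too small for comparisons with those shCtrl arrays, which was not tested. Where a cause is not named it was not tested. Genes near the array background and 3 arrays per group limit what can be seen.

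With only the groups compared, the fit called 94 genes for IL4I1 in shCtrl, 43 in shAHR1 and 23 in shAHR2 cells. It called 1 and 1 for shAHR1 and shAHR2 without IL4I1 (1 shared), 17 and 39 with IL4I1 (7 shared), 166 and 66 against the shCtrl baseline, and 0 for the interaction with shAHR2. A change of at least 1 on the log2 scale left 402 genes in shCtrl cells, 64 for shAHR2 without IL4I1, 128 and 109 for the hairpins with IL4I1, 366 and 240 against the baseline, and 23 and 55 shared. Leaving out dim genes, so that fewer genes were tested, gave 117 for shAHR1 without IL4I1, 147 for IL4I1 in shAHR2 cells, 1 and 0 for the interactions with shAHR1 and shAHR2, 53 shared without IL4I1, and an AHR core median of -0.24 for shAHR2 without IL4I1. Trend and robust gave 106 and 174 for the hairpins without IL4I1 (53 shared), 353 and 198 for IL4I1 in shAHR1 and shAHR2 cells, and 4 and 1 for the interactions with shAHR1 and shAHR2. Array weights gave 399 for shAHR2 with IL4I1 and 462 for IL4I1 in shAHR2 cells. Quantile normalization gave 1 gene for the interaction with shAHR2 and 1 with the mean of both. Slopes for genes called in the shAHR cells were 1.01 and 0.951, a choice of genes that favours higher slopes. Of the 240 list tests 5 passed with an estimated correlation and 30 with fry, against 69. Scaling moved the median of all genes by at most 0.0385.

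With the replicate number as a block, the counts were 372 and 235 for IL4I1 in shAHR1 and shAHR2 cells, 867 in shCtrl cells, 79 and 159 for the hairpins without and 281 and 243 with IL4I1, and 877 and 681 against the baseline. The interactions gave 0, 2 and 4 genes, the shared calls were 42 and 117, and 65 list tests passed. In shAHR1 against shCtrl cells without IL4I1, where the numbers pair the arrays, the block kept the 6 list calls. Elsewhere not every same-numbered pair exceeded 0.1, but 14 of 18 arrays correlated best with an array of their own number. Deviations correlated at 0.063 on average between same-numbered arrays of different groups, against -0.031 between other numbers. This is a hint from the data of a replicate effect that the main fit leaves in its spread.

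Leaving out 1 array in turn gave, from lowest to highest, 250 to 1065 genes for IL4I1 in shCtrl, 34 to 211 in shAHR1 and 22 to 335 in shAHR2 cells. For shAHR1 and shAHR2 the ranges were 22 to 74 and 44 to 109 without IL4I1 (17 to 39 shared), 82 to 205 and 75 to 168 with IL4I1 (39 to 94 shared), and 240 to 837 and 219 to 720 against the baseline. The interactions gave 0 to 3 with shAHR1, 0 to 3 with shAHR2 and 0 to 3 with the mean of both. The AHR core median ran from 0.60 to 0.85 for IL4I1 in shCtrl cells, from -0.81 to -0.23 for shAHR1 with IL4I1 and from -0.34 to -0.16 for shAHR2 with IL4I1. The slopes ran from 0.541 to 0.751 and from 0.545 to 0.788, and 57 to 69 list tests passed. A group left with 2 arrays was assumed to vary like the others.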

Other observations

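All tests in this part were chosen after the results were seen, and the list of endoplasmic reticulum chaperones was written then, so its members are not independent evidence of its rise.

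Chaperones and folding enzymes of the endoplasmic reticulum were higher with IL4I1. Of 15 measured members 11 rose in shCtrl, 7 in shAHR1 and 4 in shAHR2 cells in limma, with list medians of 1.18, 0.88 and 0.60. SDF2L1 rose by 2.01 ± 0.19 (SE) in shCtrl cells, HYOU1 by 1.80 ± 0.23, MANF, a secreted stress factor, by 1.76 ± 0.17, the disulfide isomerase PDIA4 by 1.66 ± 0.16 and HSPA5, the chaperone BiP, by 1.42 ± 0.23. XBP1 (0.45 ± 0.17), EDEM1 (0.37 ± 0.24) and SEC61B (0.03 ± 0.17) did not pass. Without IL4I1 the hairpins called 0 of 15 members in limma, with 1708 and 1719 genes of any kind at an unadjusted p under 0.05. With IL4I1 they called 0 and 2 of 15, SDF2L1 (-1.03 ± 0.19) and DNAJB11 (-0.79 ± 0.17), both lower under shAHR2, with list medians of -0.33 and -0.31.

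The rise of these members did not vanish in the shAHR cells, where the lower of the changes was 0.65 (SE 0.120). Since the list was written after the results were seen, this does not decide whether the response needs full AHR levels. The noisiest array, shCtrl replicate 2, takes no part in the changes in the shAHR cells, 0.80 in shAHR1 cells (SE 0.120). Without that array the list's change in shCtrl cells was 1.11 (SE 0.134), beside 1.17 with it. The members were picked after the values were seen, so these numbers describe the members and do not test that array as a source. A rise from the protein load of IL4I1 alone, whatever the level of AHR, stays open. The list's per-array median had an interaction of -0.45 (SE 0.147) with both hairpins, but its members were picked after the change in shCtrl cells was seen, which favours such a value, 0 of 15 members passed for an interaction, and IL4I1 protein was not measured. An influence of AHR on the rise may exist and was not decided by this value.

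The ATF4 list may respond to IL4I1 without full AHR levels, but the shAHR cells alone do not settle it. As given above, its members were not called there over all genes, and the list did not pass there with an estimated correlation. The lower of its changes in the shAHR cells was 0.39 (SE 0.192), beside 0.62 in shCtrl cells, and its per-array medians were 0.14 to 0.37 on the 9 arrays with IL4I1 and -0.77 to 0.10 on the 9 without. An exact two-sided permutation of the IL4I1 labels within each hairpin, adjusted over the 20 lists fixed in advance, gave p = 2.5e-04 (adjusted 8.33e-04), the smallest that 8000 labellings can give. The AHR core, wider AHR, NRF2, cell cycle and p53 lists reached the same p. The permutation treats the arrays of a line as independent, though the number of infections is not known. It also pools shCtrl with shAHR cells, so it does not test whether full AHR levels are needed. The reference genes changed by -0.12 (exact p = 0.0025, adjusted 0.00625), a small shift on the log2 scale.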
